A study of Rattus norvegicus with 8 samples.

How the data were processed

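Messenger RNA of the uterine-placental interface was measured by bulk RNA-seq in pregnant rats collected at gestational day 13.5, with 4 libraries from rats given the oil vehicle and 4 from rats given TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin) at gestational day 6.5. Groups and replicate numbers were taken from the sample titles. The oil libraries titled 1 to 4 have the same numbers in the file's column names, but the TCDD libraries titled 1 to 4 are numbered from 2 to 5 there, so a number shared by an oil and a TCDD title is not shared in the file. Libraries were made from poly-A RNA, per the labels' protocols. The aligner, the counting tool and the annotation release are not given in the sources used here.

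The deposited table holds one RPKM value (reads per kilobase of transcript, scaled to the library's mapped reads) per transcript and library, made by the authors, per the file headers. It lists 33654 transcripts of 26121 gene names, of which 5193 have several transcripts and 7206 are at 0 in all libraries. The same table holds the p-value, the false discovery rate corrected p-value and the signed fold change of the authors' test of TCDD against oil with tagwise dispersions, per the file headers. The submitters' processing notes name the build Rnor 5.0, but 4437 gene names are contig names of a style that starts with AABR07 and 0 start with AABR06, so the build behind the gene models remains unsettled and no coordinates are given. Gene names are those of the file. Of the 327 list symbols, 305 matched, 2 of them through an older symbol in a RefSeq table of assembly GRCr8.

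Depth was recovered from the steps of the low values. In RPKM, the values of a transcript are whole multiples of what 1 read is worth, and short genes, 10 in all, gave the mapped reads per library. Of 4805 low transcripts checked, 4787 (99.6%) were whole multiples within 0.01 reads. Mapped reads per library were 19012077, 26796043, 20520555 and 27494358 for oil replicates 1 to 4, and 26850976, 18659309, 27440092 and 30871264 for TCDD replicates 1 to 4, a ratio of 1.65 between the deepest and the shallowest. The listed transcripts held 77.8% to 79.5% of these reads. A single read in a transcript of 1 kilobase corresponded to between 0.0324 and 0.0536 RPKM, so values near that level rest on few reads. No pair of replicates agreed within sampling noise: chi-square per gene over the recovered reads ran from 15.65 to 172.98, so each library was counted as 1 sample.

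RPKM was summed over the transcripts of a gene. Genes with at least 0.5 RPKM in at least 4 libraries were kept, which left 12696. The test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(RPKM + 0.1), all 8 libraries and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(RPKM + 0.1) scale, which understates the change of low genes. The design fixed before the data were examined named a count test for count tables and this limma test for RPKM; because the table holds RPKM, the limma test was used. The 23 gene lists, also fixed before the data were examined, were tested with camera (limma) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Adjusted p-values of lists are over the 23 lists. The labels name no litter, batch or separate culture, so the p-values measure the spread between these samples.

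Genes named by rule were every measured AHR target, Ahr, Arnt and Aip; the 8 largest changes in each direction among called genes with a proper symbol, a mean of at least 1 RPKM and groups that did not overlap; and from each other list up to 4 called members with the smallest p, or 1 where none was called. This gave 65 genes. Genes named outside the rule are said to be so. Members of the Prl, Klr, Gzm, Ceacam and Hb families have related copies whose reads the counting could split. How alike the copies are was not tested, so the individual values of these genes are uncertain to an unknown degree.

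The limma step was tested on simulated data made from these libraries, with 200 of 12696 genes changed in each of 10 rounds. For TCDD against oil it recovered 25.8% of genes changed by 0.5 on the log2 scale, 67.2% at 1, 91.4% at 2 and 98.6% at 4, and 5.6% of its calls were false. The simulation drew each gene independently, without the differences that genes of a real library share, so these rates may not hold for the real data. Alternatives fixed before the data were examined were quantile normalization, no filter on low values, a pseudocount of 1, limma-voom on the recovered reads, a replicate block, leaving out each library, a fold threshold and an estimated list correlation. Alternatives set for count tables were not run. Alternatives added after the data were seen were single transcripts, median-of-ratios scaling, a hepatocyte marker score or a smooth muscle score as a covariate, and leaving out oil 3 and TCDD 3 together. Fits that leave out libraries kept the same 12696 genes. This was decided after a first run had reapplied the filter to 7 libraries, which dropped Cyp1a1 whenever a TCDD library was left out; the reapplied filter gave 75 to 745 genes higher and 293 to 1028 lower. The count of 35 splits of the libraries used the same limma and camera steps. The 181 groups of genes that share a symbol stem were formed after the data were seen.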

Results

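The uterine-placental interface is the part of the uterus next to the placenta, where uterine immune cells, blood vessels, muscle and invading trophoblast meet. RNA was sequenced from this tissue at gestational day 13.5 in 4 libraries from rats given oil and in 4 libraries from rats given TCDD at gestational day 6.5. TCDD is a dioxin that binds the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. Each library held between 18659309 and 30871264 mapped reads. The comparison asks which transcripts of this tissue differ after TCDD exposure.

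Among the named genes, Cyp1a1 and Ahrr, both of the AHR response, had the smallest limma adjusted p. Cyp1a1, a monooxygenase and the standard AHR target, was at 0.0311 ± 0.0532 RPKM (SD, n = 4) in oil and 28.6 ± 4.51 (SD, n = 4) with TCDD. Its log2 fold change was 7.84 ± 0.25 (SE), with a limma adjusted p of 5.665e-06. Ahrr, the AHR repressor, went from 0.0421 ± 0.0133 to 2.23 ± 0.529 RPKM (SD, n = 4 each), a log2 fold change of 4.01 (limma adjusted p = 0.0005573). Cyp1b1, a related monooxygenase, went from 3.18 ± 1.19 to 15.0 ± 2.79 RPKM (SD, n = 4 each), a log2 fold change of 2.25 (limma adjusted p = 0.005731). Of the 7 measured AHR targets, 3 rose and 4 did not pass; adjusted over the list alone, 5 rose. Nqo1 had a log2 fold change of 0.53 (limma adjusted p = 0.05833) and passed without oil 3 (adjusted p = 0.04921) or TCDD 1 (adjusted p = 0.04551). Aldh3a1 had a log2 fold change of 1.20 (limma adjusted p = 0.06026) and passed without TCDD 2 (adjusted p = 0.02513). With quantile normalization both passed (adjusted p = 0.03601 and 0.0496) and limma called 5 of the 7 targets. The same held with the replicate block (limma adjusted p = 0.02703 and 0.02694, and 5 of the 7 targets). Nqo1 also passed with median-of-ratios scaling (adjusted p = 0.03547) and without oil 3 and TCDD 3 together (adjusted p = 0.03348). Over the 17 alternative fits the adjusted p ran from 0.02703 to 0.5438 for Nqo1 and from 0.02513 to 0.4215 for Aldh3a1, which did not pass in 11 and 14 of them. Tiparp and Xdh had log2 fold changes of 0.05 and 0.03. The list was called higher by camera (adjusted p = 7.817e-06; adjusted p = 0.05449 with an estimated correlation). Of the 17 alternative fits, Cyp1b1 lost its call in 1, with a smooth muscle marker score as a covariate (limma adjusted p = 0.1164; 0.00134 to 0.1164 over all 17), where its log2 fold change went from 2.25 ± 0.23 to 1.89 ± 0.33 (SE), whereas Cyp1a1 and Ahrr passed in all 17. Every TCDD library lay above every oil library for Cyp1a1, Ahrr and Cyp1b1.

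**Figure D1:**
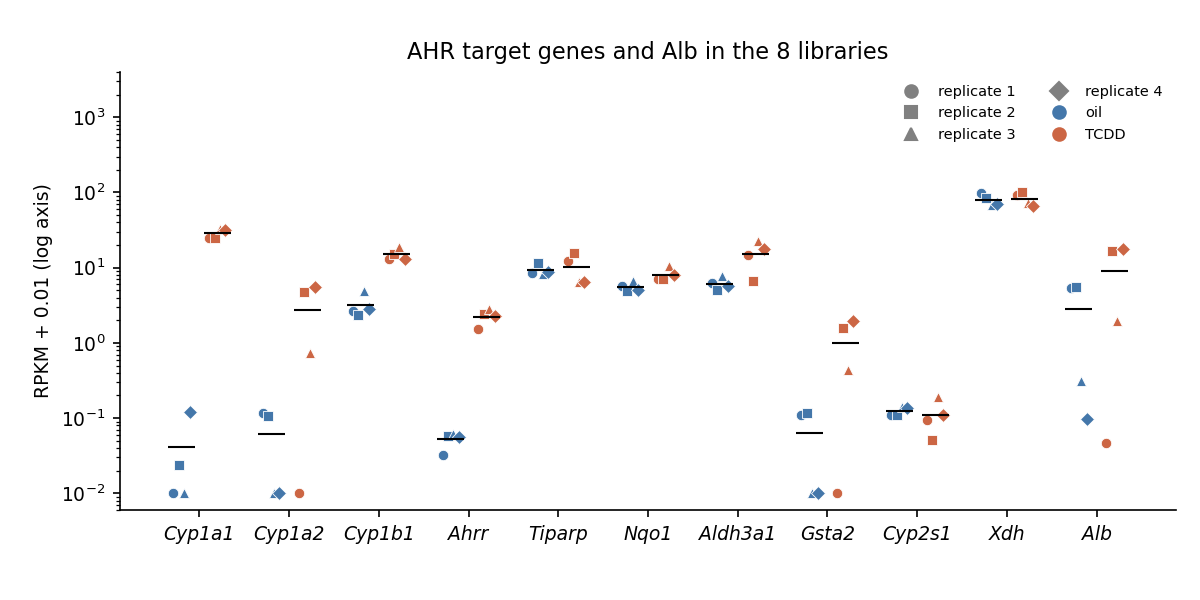
RPKM + 0.01 on a log axis for the AHR target genes and Alb in each library, with oil in blue, TCDD in orange, a marker shape per replicate number and a bar at each group mean. Cyp1a1 lies between 24.5 and 32.9 RPKM in the TCDD libraries, including TCDD 1, where Alb is at 0.036.

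Cyp1a2 and Gsta2, AHR targets that are abundant in liver, fell below the filter and were not tested. Cyp1a2 was at 4.68, 0.73 and 5.57 RPKM in TCDD replicates 2, 3 and 4 and at 0 in TCDD 1. Alb, the serum albumin transcript of hepatocytes, chosen after its values were seen, was at 16.9, 1.94 and 17.7 RPKM in the same 3 libraries and at 0.036 in TCDD 1. In oil replicates 1 and 2, Alb was at 5.44 and 5.57 RPKM and Cyp1a2 at 0.108 and 0.0958. Cyp2s1 was at 0.113 ± 0.016 RPKM in oil and 0.101 ± 0.0581 with TCDD (SD, n = 4 each) and was not tested. The receptor and its partners had small differences that did not pass: Ahr had a log2 fold change of -0.03, Arnt of -0.04 and Aip of 0.07. Of the 7 measured AHR pathway components, 1 rose, and 1 adjusted over the list alone: Arnt2, an Arnt paralog, had a log2 fold change of 1.02 (limma adjusted p = 0.03841). It did not pass in 13 of 17 alternative fits (adjusted p from 0.03405 to 0.2246), among them those without oil 1, 2 or 3 or any 1 TCDD library, with adjusted p of 0.05293 to 0.1069. The list was not called (camera adjusted p = 0.5764), with a median of -0.03 and a mean of 0.12.

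Across the transcriptome, 409 genes were higher and 958 lower with TCDD at a limma adjusted p under 0.05, of 12696 tested. A log2 fold change of at least 1 in size was seen for 115 of the higher and 468 of the lower genes. The groups did not overlap for 2442 genes (19.2%), where chance gives 2.9%. These counts changed when 1 library was left out, in fits with fewer samples, and the cause was not tested. At an unadjusted p under 0.05 in limma, 1069 genes were higher and 1594 lower without oil 1, against 1409 and 1930 with all 8 libraries. Genes higher numbered 79 without oil 1, 156 without oil 2, 181 without oil 4, 763 without TCDD 1, 159 without TCDD 2, 213 without TCDD 3 and 166 without TCDD 4. Genes lower numbered 317 without oil 1, 511 without oil 2, 552 without oil 4 and 535 without TCDD 2. With a smooth muscle marker score as a covariate, limma called 2 genes higher and 0 lower, with 768 and 1512 at an unadjusted p under 0.05, and 47 of the 62 tested named genes lost their call. With a hepatocyte marker score as a covariate it called 127 higher and 422 lower, and 20 named genes lost their call, while all 1367 called genes had the same direction and the median gene kept 99.3% of its log2 fold change (median SE 0.16 before and 0.18 after). Without oil 3 and TCDD 3, the libraries farthest from their groups on the first principal components, 259 genes were higher and 780 lower. Of the 62 tested named genes, 32 lost their call without oil 1, 17 without oil 2, 11 without oil 3, 10 without oil 4, 3 without TCDD 1, 14 without TCDD 2, 13 without TCDD 3 and 12 without TCDD 4. The authors' deposited table tests transcripts with tagwise dispersions. There, 99 transcripts of 90 genes were higher and 287 of 272 genes lower at a false discovery rate under 0.05. Of these genes, 88 and 272 were tested here, and limma called 63 higher and 244 lower.

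Markers of uterine natural killer (NK) and cytotoxic cells, the main lymphocytes of this tissue, were lower as a list by camera. Of the 18 measured members, 11 had negative and 7 had positive log2 fold changes. Prf1, which encodes perforin, went from 973 ± 28.0 to 206 ± 119.8 RPKM (SD, n = 4 each), a log2 fold change of -2.52 ± 0.50 (SE; limma adjusted p = 0.01783), with every TCDD library below every oil library. Gzmb, Nkg7, Klrg1, Il2rb, Ccl5, Faslg and Eomes also fell, by log2 fold changes of -2.32, -1.95, -2.26, -1.64, -1.57, -1.86 and -2.01. The granzyme genes Gzmf and Gzmm did not pass (log2 fold changes of -1.56 and 0.23, limma adjusted p = 0.06815 and 0.8345). Gzmb, Gzmf, Gzmm, Il2rb, Ccl5, Faslg, Eomes and Ncam1 were chosen after their values were seen. Of 18 measured members, 8 fell, 2 rose and 8 did not pass; adjusted over the list alone, 10 fell and 2 rose. Without oil 1, limma called 0 lower and 0 higher (10 and 3 at an unadjusted p under 0.05). It called 2 lower without oil 2, 5 without oil 3, 3 without oil 4, 3 without TCDD 2 and 5 without TCDD 4, and 1 higher without oil 2, oil 4, TCDD 1 or TCDD 4. The members that rose were Klrd1, a lectin-like receptor chain whose paralogs can share reads, at 1.20, and Ncam1, an adhesion molecule that other cells also make, at 1.92. Camera called the list lower (adjusted p = 0.03854, and 0.6907 with an estimated correlation), while fry did not (fry false discovery rate 0.2154). That call was lost without oil 1, 2 or 4 or TCDD 4, with adjusted p of 0.06135, 0.06825, 0.1387 and 0.07998 (0.00356 to 0.6907 over 18 alternatives). Without oil 1, limma adjusted p was 0.05707 for Prf1, 0.0534 for Klrg1, 0.05494 for Nkg7 and 0.05238 for Klrd1, and without oil 2 it was 0.05024 for Prf1. With the hepatocyte marker score as a covariate the list's adjusted p was 0.128, at a median of -0.97 against -1.05 without it, and limma called 0 lower (10 at an unadjusted p under 0.05) and 2 higher. Smooth muscle markers were higher in 3 of the 4 TCDD libraries than in any oil library, and with that score as a covariate limma called 0 of the 18 members (3 lower and 5 higher at an unadjusted p under 0.05; list median -0.26, camera adjusted p = 0.6718).

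T cell receptor complex genes fell too. Cd3g, Cd3d and Cd3e had log2 fold changes of -2.08, -1.62 and -1.47 (limma adjusted p = 0.009851, 0.01139 and 0.03115). They were 3 of 5 measured T and B cell markers, and 4 fell adjusted over the list alone. Cd3e did not pass without oil 1, 3 or 4 or TCDD 2 or 4 (adjusted p of 0.08865, 0.06516, 0.08498, 0.07975 and 0.0692; 0.02334 to 0.1184 over the 17 alternatives). Camera called this list lower (adjusted p = 0.00571, and 0.2693 with an estimated correlation). Of its 11 members in the file, 5 passed the filter on low values. Without that filter the median over 11 genes was -0.09 against -1.47, with a camera adjusted p of 0.04923. Limma then called 3 lower and 0 higher (5 and 1 at an unadjusted p under 0.05). Among 13 macrophage and myeloid markers, 2 fell: Fcer1g and Tyrobp, signalling adaptors that NK cells also use, at -1.47 and -0.84; 2 fell adjusted over the list alone. Tyrobp did not pass without oil 2, 3 or 4 or TCDD 2 or 4, with adjusted p of 0.06551, 0.06107, 0.07076, 0.05067 and 0.06152 (0.02601 to 0.2783 over the 17 alternatives). That list was not called (camera adjusted p = 0.4262), with a median of 0.06, a mean of -0.23 and a test direction of lower.

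Trophoblast genes were higher with TCDD. Of 10 measured invasive trophoblast markers, 6 rose (3 without oil 1) and 4 did not pass, and 8 rose adjusted over the list alone. Prl7b1, a prolactin-family gene of invasive trophoblast, went from 3.21 ± 4.79 to 61.7 ± 35.3 RPKM (SD, n = 4 each), a log2 fold change of 5.85 ± 1.30 (SE; limma adjusted p = 0.02647). Tfap2c, a trophoblast transcription factor, rose by 1.92, Mmp12, a matrix protease, by 3.34 and Igf2, a growth factor, by 1.89. Camera called the list higher (adjusted p = 1.507e-06; adjusted p = 0.2693 with an estimated correlation). Of 7 measured junctional zone and giant cell markers, 6 rose, and 6 adjusted over the list alone. All 6 were prolactin-family genes, whose related copies could share reads, though this was not tested. Limma called 1 of these 7 without oil 1, 2 without oil 2, 2 without TCDD 3, 2 without oil 3 and TCDD 3 together and 1 with limma-voom. Prl4a1 had a log2 fold change of 6.86 and Prl2c1 of 5.18 (limma adjusted p = 0.03008 and 0.02348). Camera called this list higher as well (adjusted p = 0.0001863, and 0.2693 with an estimated correlation). Of its 14 members in the file, 7 passed the filter on low values. Members near 0 in oil, such as Prl8a9 (mean 0.00867 RPKM), could pass only through their values with TCDD. The share that rose was thus in part set by the filter. Without it, limma called 6 of 12 higher, at a median of 3.29 (camera adjusted p = 4.941e-05). Tpbpa, a junctional zone gene chosen after its values were seen, was at 0.247 ± 0.117 RPKM in oil and 0.196 ± 0.201 with TCDD (SD, n = 4 each) and was not tested. In oil, Prl7b1 was at 2.41 and 10.2 RPKM in replicates 3 and 4, and at 0.209 and 0 in replicates 1 and 2. Prl7b1 did not pass in 7 of 17 alternative fits (adjusted p from 0.01025 to 0.2291) and Prl4a1 in 8 (0.01387 to 0.2721). Without oil 1, oil 2, TCDD 2, TCDD 3 or TCDD 4, the adjusted p of Prl7b1 was 0.08, 0.05, 0.05886, 0.05963 and 0.05423, and that of Prl4a1 was 0.08476, 0.06673, 0.05934, 0.07186 and 0.05572. That of Prl2c1 was 0.07184, 0.06345 and 0.05135 without oil 1, oil 2 or TCDD 3. With the smooth muscle score as a covariate limma called 0 of 10 invasive and 0 of 7 junctional zone markers (6 and 6 higher at an unadjusted p under 0.05), while camera called both lists (adjusted p = 8.224e-06 and 3.155e-05), at medians of 1.88 against 1.90 and of 4.60 against 4.03 without it.

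**Figure D2:**
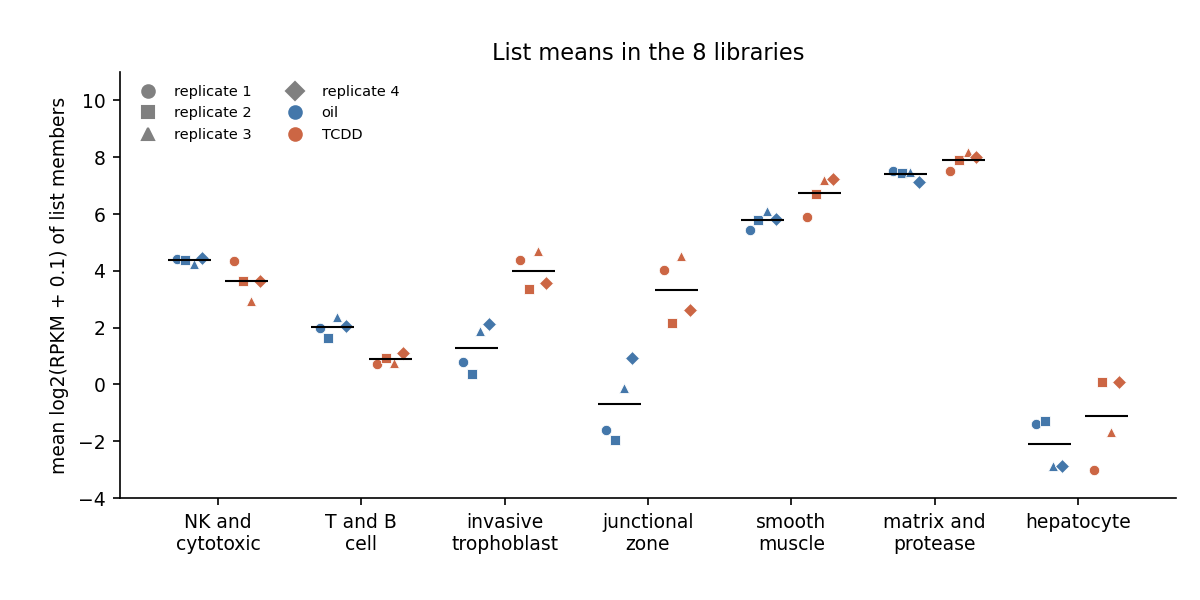
Mean log2(RPKM + 0.1) of the measured members of 6 lists and of the hepatocyte markers in each library, with oil in blue, TCDD in orange, a marker shape per replicate number and a bar at each group mean. The invasive trophoblast mean lies at 3.34 or more in every TCDD library and at 2.13 or less in every oil library, while the smooth muscle mean of TCDD 1 (5.90) lies among those of oil.

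By camera, matrix and smooth muscle genes were higher as lists. Of 17 extracellular matrix and protease genes, 6 rose, and adjusted over the list alone 8 rose and 1 fell. The 6 became 1 without oil 1, 3 without oil 2, 2 without oil 3, 1 without oil 4 (with 1 lower), 1 without TCDD 2, 2 without TCDD 3, 2 without TCDD 4, 2 without oil 3 and TCDD 3 together and 1 with the hepatocyte score as a covariate. Mmp11, a matrix metalloprotease, went from 0.763 ± 0.299 to 7.13 ± 2.13 RPKM (SD, n = 4 each), a log2 fold change of 3.07 ± 0.27 (SE; limma adjusted p = 0.005196). Timp2, Col4a2 and Plau rose by 0.57, 0.79 and 0.98, but without 1 library their adjusted p reached 0.06675 (oil 1), 0.07383 (oil 4) and 0.08723 (TCDD 2), and 4, 6 and 6 of the 8 left-out libraries ended their calls. Camera called the list higher (adjusted p = 0.0001941; adjusted p = 0.3532 with an estimated correlation). With the smooth muscle score as a covariate its median went from 0.55 to 0.28, 0 of 17 genes were called by limma (4 higher and 1 lower at an unadjusted p under 0.05) and camera did not call it (adjusted p = 0.07571; 4.164e-05 to 0.3532 over 18 alternatives). Of 12 smooth muscle markers, 2 rose, Myocd at 1.45 and Synpo2 at 0.84, and 10 adjusted over the list alone. Without TCDD 1, 11 of 12 were called higher (median 1.44 against 1.09), and without oil 1, 1 was. Myocd did not pass without oil 1 (adjusted p = 0.05389; 0.005786 to 0.1886 over the 17 alternatives). Camera called that list higher (adjusted p = 7.817e-06, and 0.3857 with an estimated correlation), while fry did not (fry false discovery rate 0.06094). Plvap, an endothelial diaphragm protein, rose by 1.05 and was the 1 of 16 endothelial markers to pass (3 without TCDD 1). Pdgfrb, a pericyte receptor, rose by 0.45, as the 1 of 19 angiogenic genes, but did not pass without any 1 library other than oil 4 (adjusted p of 0.05879 to 0.1219), and without TCDD 1 limma called 1 angiogenic gene lower. Adjusted over the list alone, 1 endothelial and 0 angiogenic genes rose. Neither of these lists was called, with camera adjusted p of 0.2142 and 0.4262; without TCDD 1 the endothelial list was called (adjusted p = 0.03767; 0.03767 to 0.6907 over 18 alternatives).

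Other lists held few called genes. Decidual and stromal markers were called higher as a list (camera adjusted p = 0.03359; adjusted p = 0.2693 with an estimated correlation) with 0 of 14 members past the limma threshold (5 higher and 1 lower at an unadjusted p under 0.05), also adjusted over the list alone; Foxo1 had the smallest p, at a log2 fold change of 0.58, and passed without oil 3 (limma adjusted p = 0.04366; 0.04366 to 0.2539 over the 17 alternatives). Without oil 3 that list's adjusted p was 0.05445, and limma called 1 decidual gene higher without oil 3 or TCDD 3, 3 higher without TCDD 1 and 1 lower without TCDD 4. Interferon-stimulated genes were called lower (camera adjusted p = 0.005889; adjusted p = 0.6907 with an estimated correlation), with 1 of 17 called, Bst2 at -0.59, and 0 adjusted over the list alone. Bst2 passed without TCDD 1, and did not pass when any other 1 library was left out (adjusted p of 0.07913 to 0.13). Camera did not call the interferon list without oil 1 (adjusted p = 0.07756) or without oil 3 and TCDD 3 together (0.08882, median -0.37 against -0.59). Proliferation genes were called lower (camera adjusted p = 0.007921; adjusted p = 0.6907 with an estimated correlation), with 1 of 13 called, Cdk1 at -0.68, and 1 adjusted over the list alone. Cdk1 did not pass without oil 1, 2 or 3 or TCDD 2 (adjusted p of 0.07955, 0.06428, 0.05441 and 0.06887), and without TCDD 1 the list's adjusted p was 0.05873. Hypoxia and glycolysis genes were called lower (camera adjusted p = 0.03854; adjusted p = 0.6907 with an estimated correlation) with 0 of 14 members called by limma (5 lower at an unadjusted p under 0.05, 3 adjusted over the list alone, 4 without TCDD 1) and Car9 at -1.14. That camera call was lost without oil 2 or 4 or TCDD 3 or 4, with adjusted p of 0.06027, 0.158, 0.1892 and 0.1119. It was also lost without oil 3 and TCDD 3 together (camera adjusted p = 0.09034). With the smooth muscle score as a covariate camera did not call the decidual list (median 0.29 against 0.42 without it, adjusted p = 0.0557), the interferon list (median -0.63 against -0.59, adjusted p = 0.3039) or the hypoxia list (median 0.017 against -0.20, adjusted p = 0.3039). The interferon median did not shrink, but the median SE of these genes went from 0.42 to 0.66. The hypoxia list was not called with the hepatocyte score either (median -0.16, adjusted p = 0.1436). Over 18 alternatives the adjusted p of the decidual list ran from 0.0236 to 0.2693, of the interferon list from 0.0001658 to 0.6907, of the proliferation list from 1.239e-07 to 0.6907 and of the hypoxia list from 0.0007769 to 0.6907.

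The remaining lists were not called by camera in the fit of all 8 libraries. Among epithelial markers Krt7, a keratin, rose by 2.11 (1 of 9, and 1 adjusted over the list alone), but not without oil 1, 2 or 4 or TCDD 3 or 4 (adjusted p of 0.06793 to 0.08472), and without oil 3 limma called 3 of the 9. The epithelial list (camera adjusted p = 0.07988) was called without oil 3 or TCDD 2 (adjusted p = 0.01377 and 0.01222; 0.01222 to 0.6907 over 18 alternatives), with limma-voom (0.0352) and with the hepatocyte score as a covariate (0.03006). Among erythroid markers the embryonic globins Hbe1 and Hbz rose (2 of 5, and 2 adjusted over the list alone; camera adjusted p = 0.4262), with 134.7 and 101.6 RPKM in TCDD 2 against at most 6.71 in the other TCDD libraries. Hbe1 did not pass without any 1 oil library or TCDD 3 (adjusted p of 0.05399 to 0.08371), nor Hbz without these or TCDD 1 (0.05701 to 0.1019), and neither passed with a pseudocount of 1 or limma-voom. Ptgs2, the inducible cyclooxygenase, rose by 1.74 (1 of 12 inflammatory genes, and 1 adjusted over the list alone; camera adjusted p = 0.3985). Me1, malic enzyme, rose by 0.88 (1 of 10 NRF2 targets, and 2 adjusted over the list alone; camera adjusted p = 0.4262). Without oil 1 the adjusted p was 0.05173 for Ptgs2 and 0.05445 for Me1; limma called 2 NRF2 targets without oil 3 or TCDD 1, and 1 inflammatory gene lower without TCDD 1 or TCDD 2. None of 5 neutrophil, 5 steroid, 11 immediate early or 8 mitochondrially encoded genes passed in limma (0, 1, 2 and 0 at an unadjusted p under 0.05), also adjusted over the list alone; the members with the smallest p were Csf3r at -0.68, Srd5a1 at 0.80, Fos at -0.56 and Mt-nd4 at 0.25. Camera adjusted p was 0.4262, 0.1242, 0.4262 and 0.4748. Fos passed without TCDD 4 (limma adjusted p = 0.03624), and the steroid list was called without TCDD 2 (camera adjusted p = 0.04957; 0.006566 to 0.4995 over 18 alternatives) and without a filter on low values (0.006566). The mitochondrial list was called higher with quantile normalization (camera adjusted p = 0.03694, median 0.20 against 0.04; 0.03694 to 0.751 over 18 alternatives). The immediate early list was called lower with the smooth muscle score as a covariate (camera adjusted p = 0.02418, median -0.57 against -0.27; 0.02418 to 0.8394 over 18 alternatives).

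**Figure D3:**
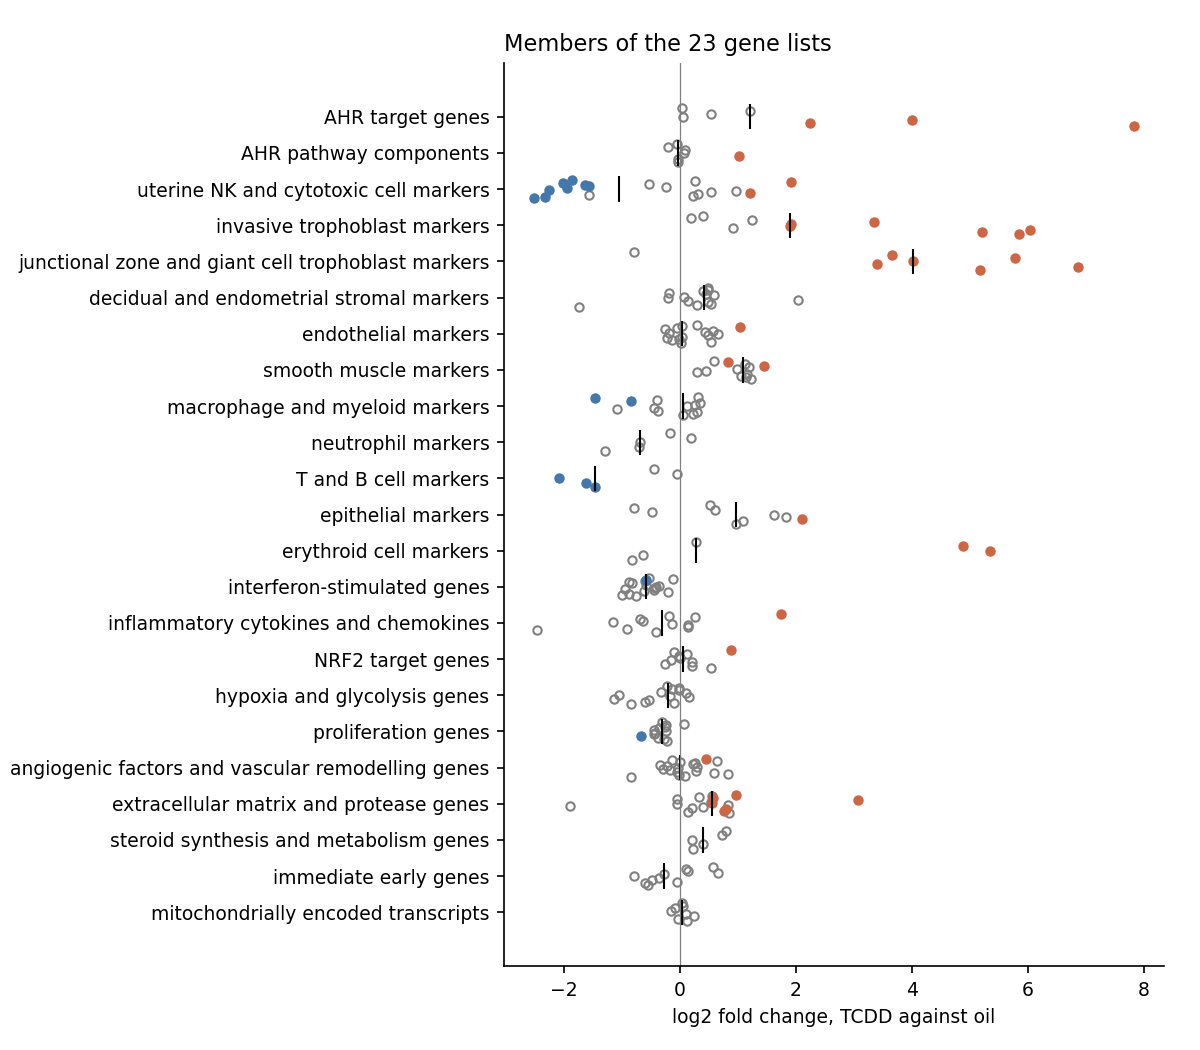
Log2 fold change, TCDD against oil, of each measured member of the 23 lists, filled orange where called higher, filled blue where called lower and open where not called, with a bar at each list's median. The largest value is Cyp1a1 at 7.84, and the 8 filled NK genes on the left lie between -2.52 and -1.57.

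By size, the named genes with the largest rises were Cyp1a1, Prl4a1, Ceacam3 (6.59), Ceacam9 (6.34), Prl2a1 (6.04), Prl7b1, Prl7d1 (5.79) and Mmp1 (5.61). The largest falls were Mepe, an extracellular phosphoglycoprotein, at -3.54, Klra5_3, a lectin-like receptor gene as named in the file, at -2.89, Dleu7 at -2.78, Havcr2, an immune checkpoint receptor, at -2.68, Rgs1, a regulator of G protein signalling, at -2.55, Ctsll3 at -2.55, Gzmn_1, a granzyme gene as named in the file, at -2.52, and Prf1. All 16 had a limma adjusted p under 0.05 and groups that did not overlap. Cyp1a1, Mepe, Klra5_3 and Rgs1 passed whichever 1 library was left out. The other 12 did not pass without oil 1, with adjusted p from 0.05019 (Ceacam3, Gzmn_1) to 0.09975 (Ctsll3).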

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

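The tests of Cyp1a2, of dilution, of NK markers falling alike, of embryonic globin and of Tpbpa were chosen only after the results were seen. So was the rule that a covariate test or the test of NK markers decides only where all fits that leave out a library fall on one side of its bound, set so that no 1 library decides.

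One library lay far from the other 3 of its group in 10 of 176 groups of named genes and lists checked, and chance flags about 1 in 20 groups (5%). Ahrr in oil 1 was at 0.0224 RPKM against 0.0465 to 0.0519. Prl8a9 in oil 4 was at 0.0347 RPKM against 0. Synpo2 in TCDD 1 was at 18.9 RPKM against 24.7 to 25.6. Myocd in oil 1 was at 0.785 RPKM against 1.08 to 1.15. Cd3g in TCDD 3 was at 0.413 RPKM against 0.893 to 0.966. Cd3d in TCDD 4 was at 1.21 RPKM against 0.595 to 0.62. Mmp11 in oil 1 was at 1.21 RPKM against 0.594 to 0.641. As mean log2(RPKM + 0.1), the AHR target list in TCDD 3 was at 3.94 against 3.70 to 3.73, the AHR pathway list in oil 1 at 4.49 against 4.61 to 4.62, and the matrix list in oil 4 at 7.13 against 7.46 to 7.52.

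Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave 1367 genes, and the highest of the others gave 25. This argues against chance for the number of genes called, but 35 splits are too few to exclude it. The other splits also hold the group difference within their sides, which widens their spread. Differences in litter or dissection that go with the groups are not tested by the splits. For the number of gene lists, the splits did not argue against chance: 2 of the 35 gave 11 lists, the real one and a split with TCDD 2 in place of oil 2. Camera also called lists in splits with 2 oil and 2 TCDD libraries on each side. Their number ran from 0 (oil 1, oil 2, TCDD 1 and TCDD 4 together) to 7 (oil 1, oil 2, TCDD 2 and TCDD 3 together). A camera call at the preset correlation can thus arise without a contrast of TCDD against oil.

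The rise of Cyp1a1, Ahrr and Cyp1b1 was set against liver RNA in the TCDD libraries. With the hepatocyte marker score as a covariate the 3 genes kept at least 98% of their log2 fold change, and at least 96.5% without any 1 library. That fit has 1 slope for both groups, so it cannot test liver RNA that holds these transcripts only with TCDD. Over the TCDD libraries Alb ran from 0.036 RPKM (TCDD 1) to 17.7. Cyp1a1 ran from 24.5 to 32.9, Cyp1b1 from 13.0 to 18.9 and Ahrr from 1.51 to 2.77. TCDD 1 held the 3 at 24.9, 13.0 and 1.51. These values argue against that source for the 3 genes. Cyp1a2 was different: its ratio to Alb varied 1.36-fold over the TCDD libraries with Alb, and it was at 0 in TCDD 1, so its reads may come from liver RNA. A larger share of liver RNA alone does not give its rise: oil 1 and 2 held Alb with Cyp1a2 at 0.108 and 0.0958 RPKM, and the lowest ratio to Alb with TCDD was 13.9 times the highest in oil. Induction by TCDD in the tissue itself stays as a hypothesis for Cyp1a1, Ahrr and Cyp1b1.

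The fall of NK genes was set against 3 explanations. Dilution by other RNA would lower other cell types alike. The median log2 fold change of the decidual, endothelial and macrophage lists was 0.14 (quartiles -0.18 and 0.47, and 0.07 to 0.20 when 1 library was left out) against -1.98 for the 8 NK genes. These 8 were picked because they were called lower in the same data, so this gap is in part set by that choice. Over all 18 members of the NK list the median was -1.05 and the mean -0.73. For the 8 genes that fell, the values argue against a dilution shared with those 3 cell types. The T and B cell and neutrophil lists, with medians of -1.47 and -0.68, were not part of this test. Nor can it exclude dilution by those 3 cell types themselves or by muscle. Fewer NK cells with every marker falling alike stays open. Of the 18 members, 11 had negative and 7 had positive log2 fold changes, and 2 were called higher, Klrd1 and Ncam1. Outside the list, Klrc2 was called higher at 1.01 (limma adjusted p = 0.02594), Klre1 (0.92) and Klri1 (0.71) did not pass, and Klra5_3 fell (-2.89). But paralogs and other cells may add to the genes that rose. For the list, limma called 0 higher without oil 1 (3 at an unadjusted p under 0.05) and 1 without oil 2, oil 4, TCDD 1 or TCDD 4. A different share of smooth muscle stays open as well. With that score as a covariate the median of the same 8 picked genes was -1.10, or 55.4% of its value. When 1 library was left out, 46.9% (without TCDD 4) to 77.3% (without TCDD 3) was kept. Limma called 0 of the 8 genes (3 at an unadjusted p under 0.05), with lower folds and larger errors. TCDD 1 had a muscle score (5.90) among those of oil (5.45 to 6.12). It held Prf1 at 345 RPKM against 934 to 995 in oil, and Nkg7 at 213 against 447 to 521. But its mean over the NK list (4.34) lay among those of oil (4.23 to 4.47), and 1 library does not decide. With the covariate, a change in NK cells with TCDD cannot be told apart from a different muscle share, because the muscle score itself differed between the groups.

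With the smooth muscle score as a covariate camera called both trophoblast lists (adjusted p = 8.224e-06 and 3.155e-05) and the median log2 fold change of the 12 genes higher with TCDD was 4.63 against 4.60 without it, which speaks against muscle share. But 0 of 12 genes were called by limma (12 at an unadjusted p under 0.05) and 27.5% of the median was left without TCDD 1, the 1 TCDD library with a muscle score (5.90) at the oil level, so this rests on that library and muscle share stays open. The ratio of Hbe1 to these genes varied 189.8-fold over the TCDD libraries, but 2.5-fold without TCDD 2, so admixed embryonic blood and trophoblast also stays open. Tpbpa differed by -0.051 RPKM between the groups, over 31 reads in all, too few to decide whether placental junctional zone was left on the sample. More invading trophoblast with TCDD is a hypothesis that cannot be told apart from a difference in dissection.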

How the results depend on the processing

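The single-transcript, median-of-ratios, hepatocyte and smooth muscle covariate fits and the fit without oil 3 and TCDD 3 were chosen only after the data were seen. From 409 genes higher and 958 lower, a fold threshold gave 115 and 468, the hepatocyte score 127 and 422, and the smooth muscle score 2 and 0 (unadjusted p under 0.05: 768 and 1512); without oil 3 and TCDD 3, 259 were higher. Leaving out 1 library gave 79 to 763 higher, 317 to 1029 lower and 9 to 13 lists; each such fit has fewer samples, and the cause of the spread between them was not tested. With the smooth muscle score all 1367 called genes kept their direction and the median gene kept 76.4% of its log2 fold change, while the median SE went from 0.16 to 0.23 (variance inflation 2.35), so smaller folds and larger errors ended the calls. Camera then called 6 lists against 11, and the test direction turned for 2: NK markers (median -0.26, camera adjusted p = 0.6718) and hypoxia genes (0.017, adjusted p = 0.3039). With an estimated inter-gene correlation camera called 0 lists, with 4 at an unadjusted p under 0.05. Fry called 6 lists in one direction: AHR targets, both trophoblast lists, decidual, T and B cell, and matrix. Of the lists called by camera, fry did not call the NK, smooth muscle, interferon, hypoxia or proliferation lists. Their fry false discovery rates were 0.2154, 0.06094, 0.2889, 0.2454 and 0.2454. Quantile normalization, no filter, a pseudocount of 1, limma-voom on recovered reads, single transcripts and median-of-ratios scaling gave 338 to 494 genes higher and 859 to 991 lower. With the replicate number of the titles as a block 533 genes were higher, 955 lower and 12 lists were called, with the epithelial list added (adjusted p = 0.03292); 9 of 12 smooth muscle markers and 5 of 7 AHR targets were called higher, against 2 and 3. Deviations of libraries with the same number in their titles correlated at 0.18, 0.29, 0.39 and -0.23 for numbers 1 to 4, and 3 of 4 oil libraries correlated best with their own number. Number 4 went the other way and the file numbers the TCDD libraries differently, so the numbers were not taken as pairs, though the first 3 leave this open. DESeq2 and leaving out the 50 most abundant genes were set for count tables and were not run. Depth limits genes near 0.0536 RPKM, which is 1 read per kilobase in the shallowest library.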

Other observations

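All tests in this part were chosen after the data were seen. Of 181 groups of genes that share a symbol stem, with at least 8 tested members, camera called 4 (0 with an estimated correlation, adjusted p = 0.9926 for each of them). The matrix metalloproteases (Mmp) were higher, with a median log2 fold change of 0.72 over 13 genes, 5 called higher and 1 lower. Mmp3, a stromelysin, went from 25.7 ± 10.6 to 87.2 ± 18.0 RPKM (SD, n = 4 each), while Mmp13, a collagenase, went from 3.98 ± 2.15 to 0.958 ± 0.595. Prolactin-family genes were higher, 10 of 11 called, but those near 0 in oil passed the filter only through their values with TCDD. Ribosomal protein genes of the Rpl stem were lower with a median of -0.23 and 0 of 55 called; the 3 called genes of the Rps stem, Rps6ka1, Rps6ka4 and Rps6ka5, are kinases and not ribosomal proteins. These directions held with quantile normalization, median-of-ratios scaling and limma-voom. With quantile normalization the medians of the Rpl and Rps stems were smaller in size, at -0.14 and -0.11 against -0.23 for each.

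Serpinb9, an inhibitor of granzyme B, was at 121 ± 21.2 RPKM in oil and 46.5 ± 6.37 with TCDD (SD, n = 4 each; limma adjusted p = 0.006181). Irf8, a transcription factor of myeloid and lymphoid cells, was at 88.6 ± 7.88 and 25.2 ± 12.0 RPKM (SD, n = 4 each; limma adjusted p = 0.01228). Efemp1, a matrix glycoprotein, was at 147.0 ± 27.4 and 443.6 ± 55.6 RPKM (SD, n = 4 each; limma adjusted p = 0.005731).

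Single libraries held values above the rest of their group. Gzmc, a granzyme gene, was at 695 RPKM in TCDD 4 and 66.1 in oil 3, and at most 0.77 in the other 6 libraries. Mx2, an interferon-induced gene, was at 64.4 RPKM in oil 1 and 2.10 to 20.4 in the other oil libraries. Epcam, an epithelial gene, was at 15.0 RPKM in oil 3 and 0.896 to 2.91 in the other oil libraries.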
